A study of Oryza sativa with 24 samples.

How the data were processed

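Transcripts were measured by RNA sequencing of leaf sheaths of rice seedlings in 24 libraries. Per the labels, 4 lines (A, B, C and YG) were sampled 18 h after inoculation with mycelium of the sheath blight fungus (sb) or without inoculation (ck), with 3 libraries in each of 8 groups. The authors deposited 1 table of raw counts per gene, with a column for each library and whole numbers that sum to different totals, so the deposited counts are not normalized. The submitters' processing notes name the aligner Bowtie 0.12.2 and the genome builds IRGSP-1.0, a rice build, and mm8, a mouse build, with no role or order. The counting program, its strand setting, its treatment of reads shared between genes and the annotation release are not given in the sources used here. A read placed on the wrong member of a gene family, or a donor sequence that aligns less well than the reference, would change the counts of the locus concerned. Each library was placed in its group by the title in the labels, and the column names of the table match those titles.

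The table held 38978 genes, of which 6047 had no count in any library. Totals ranged from 12702479 to 24428065 counts per library. A floor of 3 counts corresponds to 0.123 to 0.236 CPM, counts scaled to a common library total, when the deposited total of a single library is the divisor. The most abundant gene took 0.844% to 2.05% of the counts of a library, and organelle genes took at most 0.00135%. Levels are given as CPM of the counts in tested genes times the TMM factor of the library, mean ± SD of 3 libraries. No pair of libraries within a group agreed within sampling noise, so all 24 were kept as separate samples.

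Genes were tested with limma-voom (limma 3.58.1 with statmod 1.5.0, in R 4.3.3) on the deposited counts, fitted to 8 group means over all 24 libraries, with TMM scaling factors (trimmed mean of M values) and robust empirical Bayes variances. A gene was tested where at least 3 libraries, the size of a group, reached the CPM that 10 counts represent in a library of median size and the counts summed to at least 15, which left 25093 genes. P-values are two-sided, adjusted by Benjamini and Hochberg over these genes with a threshold of 0.05. The planned quasi-likelihood test of edgeR was not used, and limma-voom was chosen instead of it before any result was seen, because the mixed column separators of the table kept its unit from being read by a check for count models. TMM, median-of-ratios and upper-quartile factors were computed from their definitions without edgeR. Responses are inoculated minus control within a line, the mean response is their average over the 4 lines, and differences of response are interaction contrasts, with a test on 3 degrees of freedom over all lines. The core response counts genes past the threshold with the same sign in each line. Fold changes against controls near 0 counts depend on the offset that voom adds, so levels are given beside them; where every control library held 0 counts, a fold is a lower bound against 3 counts over the group.

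For the chromosome windows, genes past the threshold with the same sign in control and inoculated comparisons were counted in windows of 50 consecutive tested genes, in the order of the locus identifiers. Each window was set against all tested genes with a position by a one-sided hypergeometric test, adjusted over windows. Neighbouring genes are not independent replicates. For the overlap of B with C, which share the YG libraries, 10 simulated sets with equal group means were drawn, and the overlap was also computed between the control comparison of one line and the inoculated comparison of the other, which have no library in common.

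Gene lists and the rule for named genes were fixed before the data were examined, as were the groups, the contrasts and the first set of other settings. The lists were to be filled by gene names, or by locus identifiers set by hand from general knowledge where names were missing. The deposited table does not pair identifiers with names, and the reference table of assembly ASM3414082v1 matched 1 of 37849 locus identifiers and 100 of 112 organelle genes. Of 25 lists, 11 had identifiers in the table, with 49 loci in all and 47 tested, and 14 were not used here. The 11 lists were pathogenesis-related proteins, chitinases and beta-1,3-glucanases, diterpenoid phytoalexin synthesis, phenylpropanoid and lignin synthesis, jasmonate synthesis and signalling, ethylene synthesis, WRKY transcription factors, receptor kinases, the MAP kinase cascade, SWEET sugar transporters and, as a marker of another cell type, shoot meristem. The membership of a locus in a list is therefore not drawn from the files. Lists with 5 or more tested members were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and fry beside it. Under the rule, genes named in the text are list members with the largest changes, members singled out by the comparison of a line with YG, and each gene of a count of 5 or fewer; loci outside the lists are limited to 2 that rose and 2 that fell, taken by fold change of the mean response. A level of at least 5 CPM was required, except for the leading members of each list and the genes of small counts.

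Other settings set beforehand were median-of-ratios and upper-quartile factors, no low-count filter, a minimum count of 50, the replicate number as a block, only the groups compared in the fit, a test against a fold change of 2, windows of 25 and 100 genes, the other set tests and leaving out each library in turn. Those chosen after seeing the data were limma-trend, every library thinned to the smallest total, YG_ck replicate 1 and B_ck replicate 3 left out together, and lists with 2 or more tested members. The scripts were tested on simulated data drawn from the real means and library sizes. For the response in YG, 36.4% of 99 genes changed by 2-fold and 80.8% of 99 changed by 4-fold were recovered among 24737 genes, with 2.50% false calls. For the response of A against YG these shares were 19.2% and 56.1% of 198 genes each, with 3.25% false calls. In the simulated comparison of B with YG, 3 of 3 planted windows were recovered and 1 other window passed. Each planted window held 25 genes raised 4-fold in B, with no other line difference set in both states. Windows with fewer changed genes were not simulated.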

Results

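The transcriptome of rice (Oryza sativa) leaf sheaths was profiled by RNA sequencing in 4 lines named A, B, C and YG. The series describes 3 chromosome segment substitution lines that differ in resistance to sheath blight, together with the parent Koshihikari; such lines carry pieces of a donor's chromosomes in an otherwise constant background. The labels do not spell out YG or give the resistance of each letter, and YG served here as the line against which A, B and C were set. Seedling sheaths were taken 18 h after inoculation with mycelium of the sheath blight fungus or without inoculation. For controls no sampling time is given, so effects of handling or harvest time are not separated here from those of the fungus. Each of the 8 groups held 3 libraries, 24 in all, and a control is written ck and an inoculated sample sb. The deposited counts summed to between 12702479 per library (A_sb replicate 1) and 24428065 (B_ck replicate 3). Inoculated libraries held fewer counts than controls in A (mean total 16055937 against 21483059), B (18461464 against 23372205) and C (19948633 against 23847757), each with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. In YG the means were 20906406 and 21476820 (exact permutation p = 1). Replicates of a group correlated at 0.950 to 0.987 across genes, which are not independent replicates. The labels do not say whether replicates came from separate plants, so the p-values measure the spread between these libraries, which may be technical in part.

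**Figure D1:**
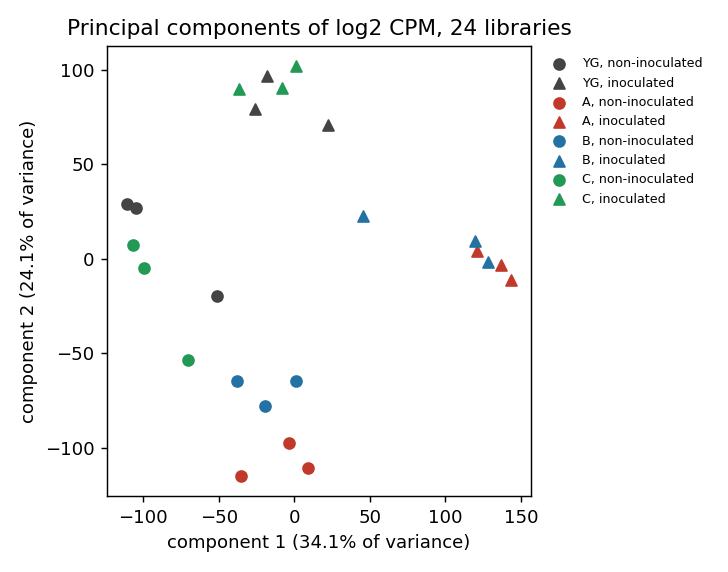
Principal components of log2 CPM over 25093 genes in 24 libraries; the horizontal axis is component 1 (34.1% of the variance) and the vertical axis component 2 (24.1%). Circles are control and triangles inoculated libraries, coloured by line; inoculated libraries of A lie far to the right of the A controls, and C lies close to YG in both states.

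The first comparison asked which transcripts changed after inoculation over the 4 lines together. Os01g0382000 held too few counts to be tested. All 4 other loci listed as pathogenesis-related proteins, which plants make under attack by pathogens, rose in the mean of the 4 lines. Os12g0555000 went from 1.32 CPM ± 0.572 (SD, n = 3) in YG controls to 529 CPM ± 132 in inoculated YG, and from 4.62 CPM ± 3.19 to 1356 CPM ± 343 in A. Its mean log2 fold change over the lines was 8.77 ± 0.50 (SE; adjusted p = 1.72e-10) in limma-voom with Benjamini-Hochberg adjustment, as for every adjusted p below. Os07g0129200 (8.15), Os12g0555500 (7.82) and Os12g0628600 (5.59) rose as well. The 3 listed chitinase and glucanase loci, enzymes that cut fungal cell walls, all rose, led by Os06g0726100 (6.58) and Os10g0416500 (5.95). Os10g0416500 reached 1117 CPM ± 244 (SD, n = 3) in inoculated A from 12.1 CPM ± 9.53 in its controls.

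All 12 listed loci of diterpenoid phytoalexin synthesis, which make antimicrobial compounds of rice, rose in the mean of the lines. Os04g0179700 stood at 244 CPM ± 54.4 (SD, n = 3) in inoculated A, 167 CPM ± 66.0 in B, 78.8 CPM ± 63.9 in C and 42.2 CPM ± 16.4 in YG. The C controls held 0 counts of it, so that it was at least 2001-fold higher in inoculated C, against a floor of 3 counts over the group. Os04g0179200 and Os12g0491800 were at 39.96 CPM ± 14.4 and 58.7 CPM ± 23.4 in inoculated YG, and at 0.0540 CPM ± 0.0936 and 0.229 CPM ± 0.191 in YG controls. Os02g0569400 had 0 counts in the controls of YG, A and C and was at least 102-fold, 937-fold and 294-fold higher after inoculation there. The weakest member, Os11g0474800, still had a log2 fold change of 3.17 ± 0.38 (SE; adjusted p = 1.61e-06). Floors here cover counting error alone. How reads shared between near-identical copies were counted is not given in the sources used here, so levels within multigene families such as these are uncertain.

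Of the 5 listed loci for phenylpropanoid and lignin synthesis, 4 rose. Os05g0427400 was the strongest, with a log2 fold change of 4.04 ± 0.37 (SE; adjusted p = 4.93e-08), followed by Os02g0627100 (1.73), while Os02g0626400 rose by only 0.25 and lost its call under upper-quartile scaling. In the list for jasmonate, a hormone of wounding and defence, 6 of 10 loci rose and 4 did not pass. Its leading members were Os03g0180900 (3.52 ± 0.47 (SE; adjusted p = 6.89e-06)) and Os03g0180800 (2.98). Among the 3 loci of ethylene synthesis, Os04g0578000 (4.38) and Os03g0727600 (2.44) rose and Os09g0451000 fell (-0.85 ± 0.22 (SE; adjusted p = 0.00537)). All 4 listed WRKY transcription factor loci rose, with Os09g0417800 (2.25) and Os09g0417600 (1.62) in front. The 2 loci of the list of wall-associated and LysM receptor kinases, Os03g0133400 (0.73) and Os08g0538300 (0.46), rose by small amounts. In the MAP kinase list Os03g0285800 rose (1.86) and the other locus did not pass, and neither of the 2 SWEET transporter loci passed. Adjusted over the list alone, the counts were the same in each of these lists except jasmonate, where 7 of 10 rose.

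In total 4629 of 25093 genes rose and 2381 fell in the mean response. Under upper-quartile scaling the split turned to 3749 higher and 5039 lower, so the balance between the directions is not fixed by these counts. Outside the lists, genes were ranked by fold change where the estimates of all 4 lines had the same sign and the controls or the inoculated libraries averaged at least 5 CPM. Os12g0240900 and Os04g0104900 came first among those that rose. Os12g0240900 was at 72.0 CPM ± 47.9 (SD, n = 3) in inoculated YG, with 0 counts in the YG controls. Os04g0104900 was at 41.9 CPM ± 20.6, again with 0 counts in the YG controls. The deepest declines under these limits were in Os05g0202800 (-4.82 ± 0.41 (SE; adjusted p = 1.93e-08)) and Os09g0319800 (-4.59 ± 0.51 (SE; adjusted p = 6.14e-07)). Os05g0202800 went from 20.8 CPM ± 9.39 to 0.634 CPM ± 0.256 in YG. The files do not pair these locus identifiers with names. In all, 3 lists had 5 or more tested members and entered the camera test of whether a list moved more than other genes. The diterpenoid list (adjusted p = 4.58e-17), the jasmonate list (adjusted p = 0.00104) and the phenylpropanoid list (adjusted p = 0.00641) all moved upward. With an estimated correlation the adjusted p was 0.0149 for the diterpenoid list, 0.228 for jasmonate and 0.111 for phenylpropanoid, so that 1 list kept its call.

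**Figure D2:**
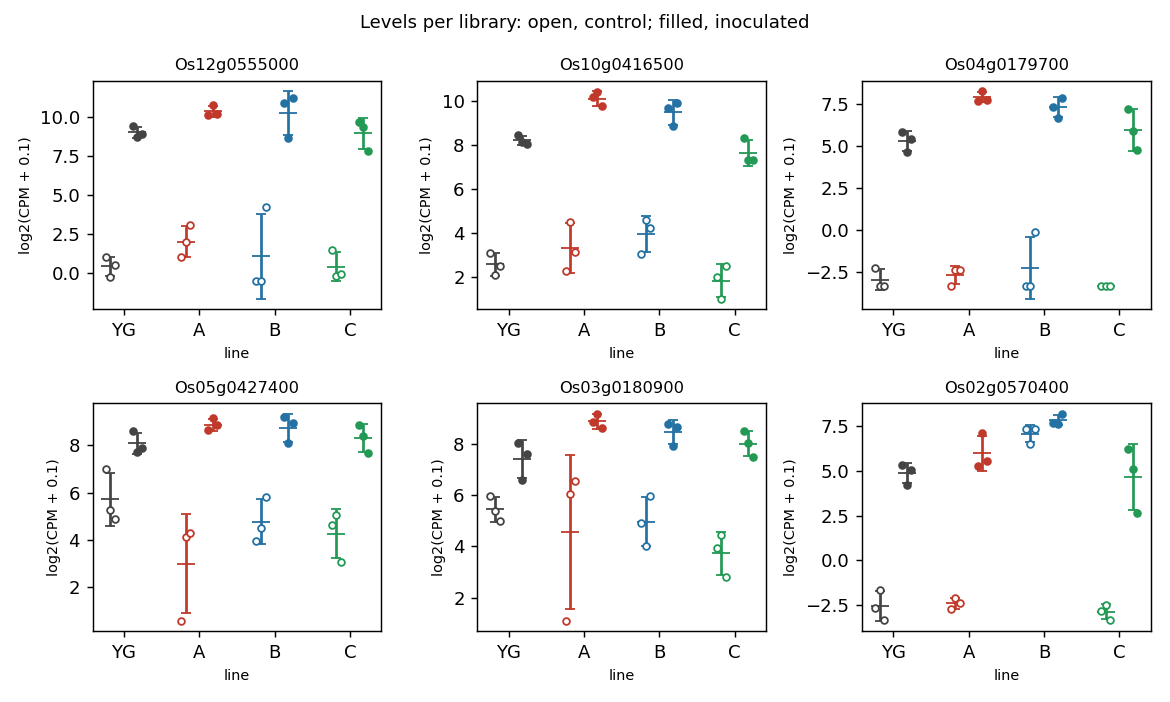
Levels of 6 listed loci in each library, as log2(CPM + 0.1) on the vertical axis and line on the horizontal axis. Open points are control and filled points inoculated libraries; the bar and whiskers are the mean and SD of 3 libraries on that scale. Os02g0570400 is high in the B controls and near 0 in the controls of YG, A and C.

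A core response was defined as the genes that passed in the same direction in each of the 4 lines on their own. It held 642 genes that rose and 26 that fell, against 1.07 and 0.00278 for independent lists of the same sizes. The lines share no libraries in this comparison, but their tests share 1 variance estimate per gene from the common fit. The lists are therefore not independent, and those 2 values are not the overlap to be had by chance. Os04g0179700, Os04g0179200 and Os12g0491800 of the diterpenoid list and Os12g0555000 and Os07g0129200 of the pathogenesis-related list were the listed core genes with the largest smallest change over the lines. All 4 pathogenesis-related and all 3 chitinase and glucanase loci rose in every line. Response sizes correlated between lines across genes, with Pearson's r from 0.689 to 0.814; genes are not independent replicates. Without YG_ck replicate 2 or replicate 3 the core held 364 or 335 genes.

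Each line was then tested on its own. In YG 1067 genes rose and 128 fell. Os12g0555000 rose in YG by a log2 fold change of 8.72 ± 1.11 (SE; adjusted p = 9.50e-05), and 5 of the 12 diterpenoid loci and 1 of the 10 jasmonate loci passed; adjusted over the list alone these were 11 and 1. In YG 0 of the 5 phenylpropanoid and 0 of the 4 WRKY loci passed in limma-voom, with 3 and 3 at an unadjusted p under 0.05, and 3 of each adjusted over the list alone. Line A had the most calls, 3433 higher and 2221 lower. There 11 of 12 diterpenoid, 3 of 5 phenylpropanoid, 6 of 10 jasmonate and 3 of 4 WRKY loci rose; adjusted over the list alone these were 12, 3, 8 and 3. Os05g0427400 went from 12.8 CPM ± 9.92 (SD, n = 3) to 469 CPM ± 83.2 in A (5.81 ± 0.83 (SE; adjusted p = 4.78e-05)), and the ethylene synthesis locus Os04g0578000 from 3.85 CPM ± 4.55 to 146 CPM ± 28.8 (6.11 ± 0.87 (SE; adjusted p = 4.25e-05)). In B 2421 genes rose and 560 fell, with 7 of 12 diterpenoid and 3 of 10 jasmonate loci among those that rose (11 and 6 adjusted over the list alone), and Os07g0129200 at 9.11 ± 1.20 (SE; adjusted p = 4.44e-05). In C 1904 rose and 276 fell, with 6 of 12 diterpenoid and 4 of 10 jasmonate loci among those that rose (11 and 6 adjusted over the list alone), and Os12g0555500 at 8.63 ± 1.21 (SE; adjusted p = 2.30e-04). Under upper-quartile scaling the split was 1916 higher and 1149 lower in B, and 1382 and 661 in C. Among the inoculated B libraries, replicate 2 was the lowest for 12 of 12 diterpenoid and 9 of 10 jasmonate loci and held Os12g0555000 at 402 CPM against 1939.8 and 2354 CPM; without it 4020 genes were called in B, with 11 diterpenoid and 5 jasmonate loci among those that rose. Without any single library in turn, the diterpenoid loci that rose numbered 3 to 5 in YG, 9 to 10 in A, 5 to 11 in B and 3 to 9 in C, and the jasmonate loci 3 to 8 in A, 0 to 5 in B, 2 to 4 in C and 0 in YG in limma-voom, with 2 to 3 in YG and 4 to 7 in B at an unadjusted p under 0.05. Leaving out a single library moved several counts by over 1.5 times. The YG count of 1195 became 584 without YG_ck replicate 2, 591 without YG_ck replicate 3, 766 without YG_sb replicate 1, the A count of 5654 became 3658 without A_ck replicate 1, and the B count of 2981 became 1882 without B_sb replicate 1, 1864 without B_sb replicate 3. The C count of 2180 became 1352 without C_ck replicate 1, 1129 without C_ck replicate 3, 1370 without C_sb replicate 1, 1322 without C_sb replicate 2. Among the B controls, replicate 3 held the pathogenesis-related locus Os12g0555500 at 14.97 CPM, and the lowest of the other libraries held 0.0380.

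**Figure D3:**
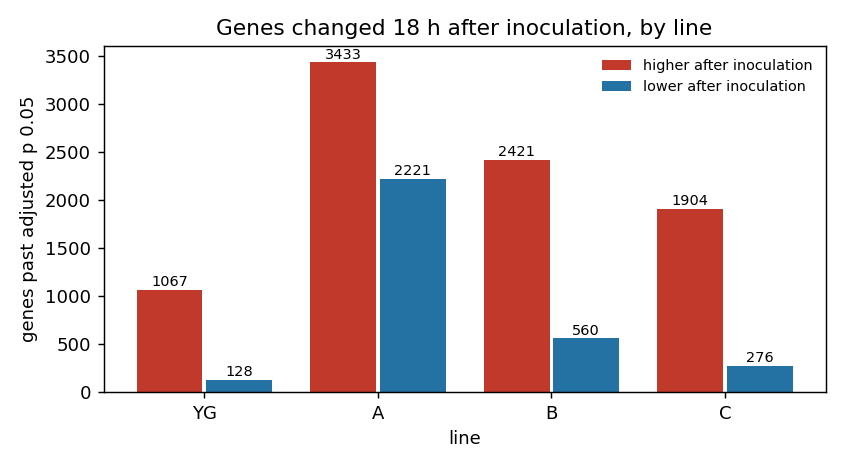
Number of genes past an adjusted p of 0.05 in the response of each line, on a linear axis from 0. Red bars count genes that rose after inoculation and blue bars genes that fell; A has 3433 and 2221, YG 1067 and 128.

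Whether the response itself differed between lines was tested with interaction contrasts. Line A differed from YG in 879 genes, and the difference mostly had the sign of the change in A. The response of A is part of this contrast, so a match of sign with A is partly built in. Whether the change was larger in A than in YG was not counted. Of all tested genes, 22.5% were called in the response of A and 4.76% in that of YG. By the sign of the estimate, all 409 genes with a higher value went up in A, and 458 of the 470 with a lower value went down; 789 of the 879 were called in the response of A and 129 in that of YG. Of the 47 listed genes 0 passed in limma-voom, with 12 at an unadjusted p under 0.05. Os04g0578000 had the difference nearest to a call, 3.77 ± 1.04 (SE; adjusted p = 0.0503), and passed after thinning and without A_ck replicate 3 or YG_ck replicate 3 (lowest adjusted p = 0.0409), and Os05g0427400 had 3.45 ± 1.08 (SE; adjusted p = 0.0777). In B 3 genes differed from YG, Os02g0601300 (1.70 ± 0.26 (SE; adjusted p = 0.0318)) and Os02g0635000 (1.24) upward and Os03g0656500 (-1.35) downward. Os02g0635000 went from 38.0 CPM ± 7.60 (SD, n = 3) to 109 CPM ± 20.8 in B, and from 36.7 CPM ± 1.37 to 44.4 CPM ± 2.34 in YG. In C 4 genes differed, Os02g0597300 (2.59 ± 0.33 (SE; adjusted p = 0.00542)), Os03g0740833 (3.57) and Os09g0543100 (1.64) upward and Os05g0380900 (-2.24) downward. Os05g0380900 went from 10.99 CPM ± 0.288 to 86.6 CPM ± 15.1 in YG and from 8.01 CPM ± 2.42 to 13.0 CPM ± 2.35 in C. These 7 loci have no name in the files and were given because each count is 5 or fewer. A test over the 4 lines together, with 3 degrees of freedom, called 258 genes; it called 0 of the 47 listed genes in limma-voom, with 7 at an unadjusted p under 0.05. The A count of 879 became 246 without A_ck replicate 1, 439 without A_sb replicate 3, 474 without YG_ck replicate 2, 574 without YG_ck replicate 3, 290 without YG_sb replicate 2, 393 without YG_sb replicate 3. The B count of 3 became 40 without B_sb replicate 2, 14 without YG_ck replicate 1, 1 without B_ck replicate 1, and 0 without any one of B_ck replicates 2 and 3, YG_ck replicates 2 and 3 and YG_sb replicates 1, 2 and 3, where limma-voom gave 1764 to 2444 genes at an unadjusted p under 0.05. The B count also became 0 in limma-voom after thinning, without YG_ck replicate 1 and B_ck replicate 3 together, and with only the groups compared in the fit (2147, 2485 and 1844 at an unadjusted p under 0.05), and 1 with either other scaling. The C count of 4 became 0 with only the groups compared in limma-voom (2737 at an unadjusted p under 0.05), 8 with limma-trend, 2 without those 2 controls, 2 without C_ck replicate 1, YG_ck replicate 1 or YG_sb replicate 2, and 1 without C_ck replicate 3, C_sb replicate 3, YG_ck replicate 2 or YG_ck replicate 3. The count over the 4 lines became 26 without A_ck replicate 1, 128 without A_ck replicate 3, 103 without A_sb replicate 1, 144 without A_sb replicate 2, 78 without A_sb replicate 3, 511 without B_sb replicate 2, 110 without C_ck replicate 1, 147 without C_ck replicate 2, 107 without C_sb replicate 2, 434 without YG_ck replicate 1, 69 without YG_ck replicate 2, 93 without YG_ck replicate 3, 31 without YG_sb replicate 2, 38 without YG_sb replicate 3.

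As a group, the jasmonate loci had larger responses than other genes in A (camera adjusted p = 6.32e-05), B (0.00431) and C (4.82e-06) relative to YG. With an estimated correlation these calls were lost, at an adjusted p = 0.382, 0.768 and 0.286. The 3 tests use the same YG libraries and are not independent. Singly, 0 of the 10 jasmonate loci passed in A, B or C in limma-voom over all genes, with 7, 3 and 6 at an unadjusted p under 0.05; adjusted over the list alone, 7 passed in A and 0 in B and C. The 7, 3 and 6 were 2, 0 and 1 without YG_ck replicate 1 or without YG_sb replicate 2, the lowest inoculated YG library for all 10 loci; the 7 were also 2 without A_ck replicate 1, and the 3 were 0 without B_ck replicate 2. Without any 1 of the other libraries they were 5 to 10, 1 to 6 and 3 to 6. In YG_ck replicate 1, the highest YG control for 10 of 10 jasmonate loci, Os10g0391400 stood at 137 CPM, against 33.1 CPM in the lowest of them. The diterpenoid list was also higher in A than in YG (adjusted p = 0.0466; with an estimated correlation, adjusted p = 0.423). In A the jasmonate list alone passed without A_ck replicate 1, A_sb replicate 2, YG_ck replicate 1 or YG_sb replicate 2. In B 0 lists passed without B_ck replicate 2, YG_ck replicate 1 or YG_sb replicate 2, with 1, 0 and 1 at an unadjusted p under 0.05 in limma's camera. The jasmonate call in C held without any single library (highest adjusted p = 0.00317).

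Control plants of each line were compared with YG controls to find differences that exist without the fungus. Line A differed most, with 4954 genes higher and 5130 lower, followed by B (2148 and 2795) and C (801 and 1168). In B a single diterpenoid locus, Os02g0570400, stood at 139 CPM ± 41.2 (SD, n = 3) in controls, against 0.0913 CPM ± 0.115 in YG, 0.0926 CPM ± 0.0414 in A and 0.0397 CPM ± 0.0389 in C (10.83 ± 2.50 (SE; adjusted p = 0.00603), B against YG). The 11 other diterpenoid loci did not pass in B controls. Jasmonate loci were lower than in YG controls for 5 of 10 members in A, 3 in B, where 1 was higher, and 4 in C. Without YG_ck replicate 1, the highest YG control for all 10, these were 2 in A, 2 in B with 1 higher, and 0 in C in limma-voom, with 5 in C at an unadjusted p under 0.05. The A count was also 2 without A_ck replicate 1, the lowest A control for all 10, and 3 without A_ck replicate 2. In B 5 were lower without B_ck replicate 3 and 2 without any other of its 6 libraries, and 0 were higher in limma-voom without B_ck replicate 3, YG_ck replicate 2 or YG_ck replicate 3 (6, 5 and 6 of either sign at an unadjusted p under 0.05). In C the count was 0 in limma-voom without C_ck replicate 1 or 3 (5 and 6 at an unadjusted p under 0.05), and 1 without C_ck replicate 2 or YG_ck replicate 2. Os10g0391400 was at 72.1 CPM ± 56.5 in YG controls and at 11.7 CPM ± 16.1, 7.87 CPM ± 8.72 and 6.76 CPM ± 3.21 in A, B and C (-3.58 ± 0.93 (SE; adjusted p = 0.00514), A against YG). The B call of Os10g0391400 was lost with only the groups compared in the fit, and the C call without any one of the 3 C_ck libraries or YG_ck replicate 1. The WRKY locus Os09g0417800 was higher in A (2.61 ± 0.83 (SE; adjusted p = 0.0178)) and B (2.92) controls, the A call being lost without A_ck replicate 2 or YG_ck replicate 2, the B call without B_ck replicate 3 or YG_ck replicate 2, and both with only the groups compared in the fit. Of the SWEET sugar transporter loci, Os11g0508600 was higher in A (2.14) and C (1.89), and Os08g0535200 was lower in A, at 1.39 CPM ± 1.11 against 57.5 CPM ± 27.4 (-5.51 ± 1.43 (SE; adjusted p = 0.00517)). Both SWEET loci also passed in B, in these directions. The MAP kinase locus Os03g0285800 was lower in the controls of A (-1.36 ± 0.40 (SE; adjusted p = 0.0117)), B (-1.25) and C (-1.53) than in YG, and the phenylpropanoid locus Os05g0427400 was lower in A (-2.67). The A call of Os03g0285800 was lost without A_ck replicate 1 or YG_ck replicate 1, the B call without B_ck replicate 1 or 2 or any 1 YG control, and the C call without any 1 C control or YG_ck replicate 1 or 2. That of Os05g0427400 was lost without A_ck replicate 1 or with only the groups compared. Under upper-quartile scaling the split was 2967 higher and 2359 lower in B, and 1370 and 927 in C. The B total of 4943 became 2311 and 2320 without YG_ck replicates 2 and 3. The C total of 1969 became 934, 1161, 1155 and 974 without C_ck replicates 1, 2 and 3 and YG_ck replicate 2.

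After inoculation, 4742 genes were higher and 5111 lower in A than in YG, 2603 and 3357 in B, and 390 and 664 in C. Diterpenoid loci were higher than in inoculated YG for 6 of 12 members in A and 5 of 12 in B. The B count was 9 without B_sb replicate 2, the lowest of its group for all 12, and 2 and 3 without B_sb replicate 3 and YG_sb replicate 2. Os04g0179700 was higher in A (2.59 ± 0.45 (SE; adjusted p = 3.58e-04)) and B (1.99 ± 0.45 (SE; adjusted p = 0.00423)), and Os02g0569400 in A (2.89). In C 1 diterpenoid locus differed, Os11g0474800, which was at 4.33 CPM ± 3.19 (SD, n = 3) against 49.3 CPM ± 11.2 in YG (-3.75 ± 0.65 (SE; adjusted p = 0.00143)). The chitinase and glucanase locus Os10g0416500 was higher in A (1.88), where Os06g0726100 of that list was lower (-1.21); in B Os06g0726100 was higher (1.32). In limma-voom 0 of the 4 pathogenesis-related loci differed from YG in A, B or C, with 0, 0 and 0 at an unadjusted p under 0.05. The ethylene synthesis locus Os03g0727600 was lower than in YG in all 3 lines, at 11.8 CPM ± 1.89 in YG and 2.46 CPM ± 0.417, 4.88 CPM ± 3.01 and 2.07 CPM ± 0.555 in A, B and C; these comparisons share the YG libraries. Its B call was lost with limma-trend and with only the groups compared in the fit. The A call of Os06g0726100 was lost with no low-count filter, with limma-trend, and without A_sb replicate 1 or 2 or any 1 inoculated YG library, and its B call with limma-trend and without B_sb replicate 3 or YG_sb replicate 3. Both loci of the receptor kinase list were higher in A and in B. Os10g0391400, lower in control plants of A, B and C, did not pass after inoculation. Its estimates there were lower too (log2 -0.74 ± 0.70, -1.08 ± 0.70 and -0.89 ± 0.69, SE). As the difference of response passed for 0 of the 10 jasmonate loci in limma-voom, a change between the states is not shown for this locus. The B total of 5960 became 3435 without B_sb replicate 1, 2918 without B_sb replicate 3, 3429 without YG_sb replicate 2, 3413 without YG_sb replicate 3. The C total of 1054 became 616 without C_sb replicate 1, 698 without C_sb replicate 2, 665 without C_sb replicate 3, 558 without YG_sb replicate 2, 620 without YG_sb replicate 3.

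Because the lines carry substituted chromosome pieces, genes that differed from YG with the same sign in both states were mapped along the chromosomes. Locus identifiers give the chromosome and the order, and tested genes were taken in 493 windows of 50; no coordinates were used. In C 560 genes differed in both states and 18 windows held more of them than the genome as a whole. The longest run covered 7 windows of chromosome 11 from Os11g0432800 to Os11g0579600, where 108 of 350 genes were called (lowest hypergeometric adjusted p = 2.64e-19). A second run of 5 windows lay at the start of chromosome 12, to Os12g0145700, and others on chromosome 6 between Os06g0218200 and Os06g0309000, with 1 window on chromosome 3. The diterpenoid locus Os11g0474800 and the SWEET transporter locus Os11g0508600 lie within the chromosome 11 run, but neither was called in both states. In C, Os11g0474800 did not pass among controls (limma-voom unadjusted p = 0.0184, adjusted p = 0.123), though it did in 2 other settings. Its estimates had the same sign in both states (log2 -2.98 among controls and -3.75 after inoculation). Os11g0508600 did not pass after inoculation, where the smallest adjusted p of the SWEET loci in limma-voom was 0.0867. The missed calls do not show that either difference is confined to 1 state. In B 2761 genes differed and 32 windows passed, on chromosomes 2, 5, 6, 7, 11 and 12. The longest runs were Os11g0595100 to Os11g0708600 on chromosome 11 (118 of 307 genes) and Os12g0100100 to Os12g0156900 on chromosome 12 (95 of 300). In A 5455 genes differed, 21.7% of those tested, and 1 window passed, on chromosome 6 from Os06g0185700 to Os06g0195900 (27 of 50 genes). Differences were larger inside the windows, with a median absolute log2 fold change among controls of 4.33 inside and 1.04 outside in C, and 2.06 and 1.13 in B. B and C passed in 8 of the same windows, on chromosomes 6 and 12, against 1.17 for independent sets and 0 in 10 simulations of unchanged lines against shared YG libraries. The first of these values leaves out the shared libraries and the simulations leave out any difference between lines, so neither gives the overlap that the sharing adds. With no YG library in common the overlap was 6 and 4 windows. The single window of A became 3, 4 and 2 windows without YG_ck replicate 2, YG_ck replicate 3 and YG_sb replicate 3, and 0 with no low-count filter.

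**Figure D4:**
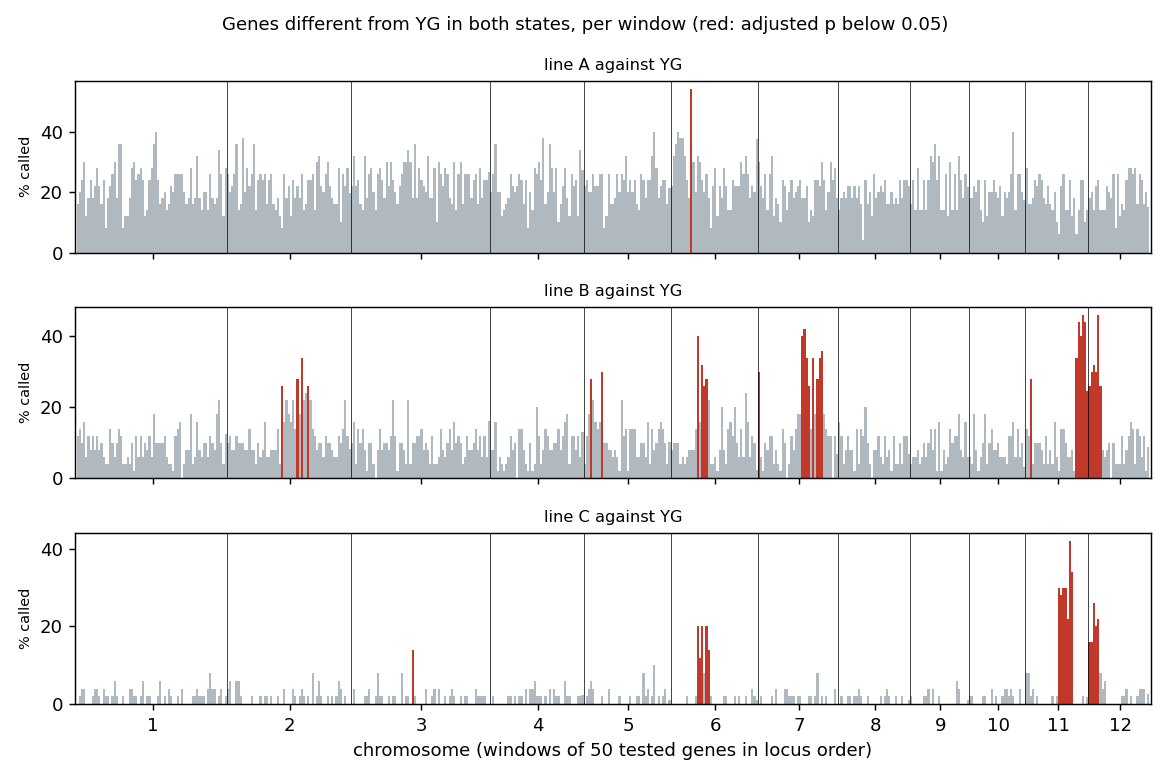
Percent of tested genes that differed from YG with the same sign in both states (vertical axis), in 493 windows of 50 tested genes in locus order along the 12 chromosomes (horizontal axis), for lines A, B and C. Red windows passed an adjusted p of 0.05; 1, 32 and 18 did so in A, B and C.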

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

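The comparison of control with inoculated differences was a test chosen only after the result was seen. Each result here passed a test of the difference between lines in the main setting, and several did not pass in other settings or tests. The response of A differed from that of YG in 879 genes; 789 of them were called in the response of A and 129 in that of YG. By the sign of the estimate, all 409 with a higher value went up in A and 458 of the 470 with a lower value went down. The response of A is part of the contrast, so this match is partly built in. Against a difference in depth or in scaling as the whole cause, 852 genes passed after every library was thinned to the smallest total, and 846 was the lower count under 2 other scalings. A different state of the control plants stays open: the difference was larger among controls for 56.3% of the genes, but 21.7% of all tested genes differed between A and YG in both states, so this share decides nothing. The size of the count leans on single libraries, since it was 246 without A_ck replicate 1, where the phenylpropanoid locus Os05g0427400 stood at 1.40 CPM against 17.4 and 19.6 CPM in the other A controls. A response of A that differs through its genotype is a further hypothesis. A different load of fungus on the sheaths stays open too, since neither lesions nor fungal mass were measured here.

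The test over the 4 lines called 258 genes. In B the response differed from YG in 3 genes, Os03g0656500 (log2 difference -1.35), Os02g0601300 (1.70) and Os02g0635000 (1.24). In C it differed in 4 genes, Os03g0740833 (3.57), Os02g0597300 (2.59), Os05g0380900 (-2.24) and Os09g0543100 (1.64). The jasmonate list moved further up than other genes in A, B and C relative to YG, with camera adjusted p = 6.32e-05, 0.00431 and 4.82e-06, and the diterpenoid list in A, with adjusted p = 0.0466; with an estimated correlation the adjusted p = 0.382, 0.768, 0.286 and 0.423. The effects on the jasmonate members were upward in the median, by log2 1.94 in A, 1.46 in B and 1.76 in C. Against YG their median was log2 -1.21, -0.67 and -1.64 among controls of A, B and C. Among inoculated libraries it was 0.78, 0.50 and 0.18, so the larger median difference lay among the controls. All 3 comparisons share the YG libraries, and YG_ck replicate 1 was the highest YG control for 10 of 10 of these loci.

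Libraries were also split in other ways into groups of the same sizes, with the mean of each line taken out first, in 100 splits per result with the real one included. In A 1 of 100 splits, the real one, gave as many as 879 genes, the highest other giving 6, and chance can be excluded. As many as 258 genes over the lines came in 3 of 100 splits, and as many as 3 genes in B in 4 of 100. Both shares are under 0.05, but the highest other splits gave 1505 and 984 genes. Chance is therefore not firmly excluded for either count. The 3 calls in B are also weak by other settings. Their count was 0 in limma-voom after thinning, without YG_ck replicate 1 and B_ck replicate 3 together, and with only the groups compared (2147, 2485 and 1844 at an unadjusted p under 0.05). It was 1 with either other scaling. In C 6 of 100 splits gave as many as 4 genes, the highest other giving 478, and chance cannot be excluded. Why some splits call several times the real count was not tested, and a structure of the samples beyond the groups stays possible. For the lists, 30 of 100 splits in A gave as many as 2, and 72 in B and 66 in C as many as 1, with 3 the highest in each and 3 lists tested, so chance cannot be excluded by these counts. Groups of 3 libraries were not tested for single libraries far from the others.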

How the results depend on the processing

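Limma-trend, thinning, the joint omission of YG_ck replicate 1 and B_ck replicate 3 and lists of 2 or more members were chosen after seeing the data. The planned DESeq2 alternative was not run. Over the settings run, 371 counts stayed within 1.5 times and 122 moved further; of the values for named genes 1625 kept side and direction, 154 fell short of the threshold, 6 passed it and 0 turned sign. The cause was not tested except where a stricter test, fewer libraries or fewer genes per test shows it. Against a fold change of 2, a stricter test, counts were 1197 for the mean response, 181, 1076, 511 and 355 in YG, A, B and C, 466, 269 and 141 among controls and 344, 324 and 140 among inoculated libraries of A, B and C; for the 3 responses against YG they were 0 in limma's treat, with 581, 198 and 147 genes at an unadjusted p under 0.05. With only the groups compared, and so fewer libraries, B gave 974, control B 1646 and inoculated B 3701, and the responses of B and C against YG 0 each in limma-voom (1844 and 2737 at an unadjusted p under 0.05). The B response against YG gave 1 gene with median-of-ratios and 1 with upper-quartile factors, and 0 when thinned or without both doubted controls (2147 and 2485); the C response against YG gave 8 with limma-trend and 2 without those controls, and the test over the lines 408 with limma-trend. Windows of A numbered 0 with no filter (limma-voom), 3 without both doubted controls, and 2 with 100 or 25 genes; those of B 21 when thinned and 17 with 100 genes. For the mean response 1 list passed with an estimated correlation and 7 lists with 2 or more members, 3 of which kept their call with an estimated correlation. In A against YG 1 list passed with either other scaling, no filter, a minimum count of 50, without both doubted controls or with lists of 2 or more, and 0 with an estimated correlation or fry (0 and 1 at an unadjusted p under 0.05); in B and C 0 passed with either (0 in each).

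Taken over all lines, the replicate numbers did not pair the libraries. Deviations correlated above 0.1 in 3 of 12 pairs of control and inoculated libraries of the same number. These were YG replicate 1 (r = 0.456), YG replicate 3 (0.238) and B replicate 3 (0.196), while YG replicate 2 had 0.0436. A pairing within YG therefore stays open. In all, 7 of 24 libraries correlated best with one of their own number. With the replicate block, the B response against YG gave 0 genes in limma-voom (2186 at an unadjusted p under 0.05), the C response against YG 8, and other counts stayed within 1.5 times; of the named genes only the inoculated A call of Os06g0726100 and the 3 B calls against YG ended. Upper-quartile factors moved the median log2 fold change of all genes by -0.11 in B and -0.15 in C, and no filter moved that of inoculated A by 0.10. Leaving out 1 library in turn, counts ranged over 6317 to 7900 for the mean response, 335 to 780 for the core, 584 to 1035, 3658 to 5677, 1864 to 4020 and 1129 to 2088 for YG, A, B and C, 246 to 1044, 0 to 40 and 1 to 6 for A, B and C against YG, 26 to 511 over the lines, 7577 to 10261, 2311 to 6348 and 934 to 1977 among controls and 7035 to 9689, 2918 to 6876 and 558 to 703 among inoculated libraries. Windows ranged over 1 to 4 in A, 23 to 34 in B and 16 to 19 in C, and lists over 3 in the mean response, 1 to 3 in A, 0 to 1 in B and 1 in C. Depth limits genes under 0.123 to 0.236 CPM of the deposited total. In the simulations 2-fold changes were recovered for 36.4% of genes in YG and 19.2% in A against YG; other group sizes and depths were not simulated.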

Other observations

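Genes that differed from YG by at least 8-fold with the same sign in both states numbered 348 in A, 307 in B and 128 in C, and most were lower in the line, 322, 242 and 106 of them. They filled 5, 21 and 13 windows of 50 genes past the threshold. In C 109 of the 128 genes lay in such windows, in B 163 of 307 and in A 37 of 348. Over all called genes, B and C shared 235 with the same sign, against 32.2 for independent lists. Part of the excess can come from the shared YG libraries. In 10 simulations of unchanged lines the count was at most 0, but these hold no difference between lines and do not measure that part. The shoot meristem locus Os03g0727000 held 0 counts in all 24 libraries, which allows up to 0.236 CPM of the deposited total in the shallowest.

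The tests in the next 2 paragraphs were chosen only after the results were seen. Line differences clustered in 32 windows in B and 18 in C, 8 of them in common. Reads of donor sequence lost in counting would lower nearly all called genes inside the windows; more of them were lower inside than outside, 74.0% against 52.8% in C and 65.2% against 59.5% in B, but 26.0% were higher in C and 34.8% in B, which argues against such loss as the whole cause and leaves a partial loss open. The YG libraries used in both comparisons are argued against as the source of the common windows, since 4 or more were shared with no library in common. A difference of YG from every other line is argued against there by the 15.2% of the common genes that were called with the same sign in A. If YG is the parent of the lines, which the labels do not state, a hypothesis consistent with these values is that the windows mark substituted segments, whose sequence variants and whose effect on other genes were not tested.

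The diterpenoid locus Os02g0570400 stood at 139 CPM ± 41.2 (SD, n = 3) in B controls, 59.6% of its inoculated level in B. A defence response already under way in the B control plants, as the source of this level, is argued against by the 11 other loci of the list. Their control level was a median 1.38% of the inoculated one, 15.4% at most. These are means of 3 libraries. B_ck replicate 3 was the highest B control for 10 of the 12 listed loci, so a weaker induction in that library stays open. Between B and YG controls the median log2 difference of the list was 1.63. A mislabelled line is argued against by 25046 genes outside the lists, over which each of the 3 B controls correlated better with inoculated B than with any other inoculated line, by at least 0.462 in r. A variant at or near the locus in B may keep it on without the fungus, as a hypothesis; its window held 8 of 50 called genes in B and did not pass, and among genes that differed by at least 8-fold it passed with the locus counted (5 of 50, adjusted p = 0.00836) and not without it (4 of 49, adjusted p = 0.0657). Reads from a related copy in a substituted segment stay open, and the response of the locus did not differ between B and YG past the threshold (-7.83 ± 2.58 (SE; adjusted p = 0.322)), except with limma-trend (-6.71; adjusted p = 0.0149).

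Splits of the libraries into groups of the same sizes were planned for each count of genes, with the real split counted among them. For the mean response 1 of 100 splits, the real one, gave as many as 7010 genes, the highest other giving 2545. Chance can be excluded for that count. For the core response 1 of 100 gave as many as 668, the highest other giving 0. Other splits of a single line called at most 3 genes, so a core of 0 was nearly fixed beforehand. This 0 therefore does not test whether the lines respond alike. The 1, 32 and 18 windows of A, B and C were each reached in 1 of 100 splits, the real one, with 0 the highest other, so chance can be excluded only for the division of the libraries; splits call few genes, so this does not test whether called genes cluster. In the simulations 1 window passed that was not planted, as many as the single window of A. The 3 lists of the mean response were reached in 15 of 100 splits, the highest other being 3, so chance cannot be excluded by this count; only 3 lists were tested, so it cannot set the real split apart and says nothing of a single list. Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05, and the real split, 1 of 10, gave the highest count in each. These counts were 1195 in YG, 5654 in A and 2180 in C, with 0 the highest other in each, and 2981 in B, with 3. Among controls they were 10084, 4943 and 1969 in A, B and C, with 1, 5 and 0 the highest others. Among inoculated libraries they were 9853, 5960 and 1054, with 0, 258 and 0.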
